A study of Mus musculus with 4 samples.

How the data were processed

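RNA sequencing measured polyadenylated transcripts in the ventricles of individual mouse embryos at embryonic day 12.5, from litter 6. Per the labels, both groups carried the floxed Hif1a allele on both chromosomes. The knockout group, written cKO, also carried Cre recombinase at the Nkx2-5 locus, which is active in heart muscle precursors, and the control group did not. There were 2 libraries per group, with the replicate numbers 2 and 3 in each.

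Per the labels' protocols, libraries were made from 500 ng of total RNA and sequenced as single reads of 75 bases. The authors deposited 1 table of expected counts per gene, which are estimated counts that need not be whole because reads that fit several genes are divided among them. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.3, RSEM 1.2.3 and the build GRCm38 were used; the annotation and the settings are not given in the sources used here. The deposited table held 38293 genes, of which 16354 were at 0 in all 4 libraries, and between 13.9% and 16.9% of the values in a library were not whole numbers. Symbols and positions came from GENCODE release 21 for mouse, on GRCm38, which gave a symbol to 36345 identifiers; those without a symbol held between 0.325% and 0.338% of a library's counts.

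The total expected count was 9980051 and 19801300 in cKO replicates 2 and 3, and 8561687 and 8989184 in control replicates 2 and 3. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filter by group at its defaults (minimum count 10, minimum total 15), which left 13711 genes. Libraries were scaled by TMM, and edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) compared the groups with Benjamini-Hochberg adjustment and a threshold of 0.05, on 2 residual degrees of freedom. Every fold change is cKO over control, adjusted p values come from this quasi-likelihood test unless another is named, CPM values are scaled by TMM, and the standard error (SE) is the log2 fold change divided by the square root of the F statistic. A fold against a group at 0 was computed against a floor of 3 counts per library and is a lower bound that covers counting error only.

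Before the data were examined, 29 gene lists were fixed from textbook knowledge. Each was tested with limma 3.58.1's camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, with adjustment over the lists. Camera with an estimated correlation and the directional test of fry, called fry below, were alternatives. The rule for named genes was fixed at the same time. It took Hif1a and Nkx2-5, and then the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes. For each list it took up to 4 members past the threshold with the smallest p, or the 1 member with the smallest p where none passed. Genes outside the rule are said to be chosen after their values were seen. The values of 2 genes that the rule took are not reported here.

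The same steps were tested on simulated counts for these 13711 genes. The test recovered 49.0% of genes changed 1.5-fold, 74.0% at 2-fold, 96.0% at 4-fold and 100% at 8-fold, with 16 false calls among 183. Camera gave p under the threshold for 0 of 100 unchanged lists. The simulated genes varied independently, so this does not check camera on lists whose genes vary together. In the real data the estimated correlation was 0.538 for the nuclear genes of oxidative phosphorylation.

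Transcripts of the called genes were compared with all GENCODE transcripts by BLAST 2.17.0. A near-identical copy had at least 95% identity over at least 300 bases on the same strand. The length was first set at 150 bases and was raised after matches through repeat elements had been seen; the change left 13 risen genes with a copy and took the fallen genes with a copy from 17 to 16. Alternatives fixed beforehand were DESeq2 1.42.0 (size factors, and its own test), upper-quartile scaling, no filter and a mean of at least 5 CPM, limma-voom, a fold threshold of 1.5 by glmTreat, the replicate number as a block, and each library left out. Other pseudocounts were planned for normalized values only and were not run.

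The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 13.1 for cKO and 5.83 for control). This statistic grows with depth and includes genes that differ by sex. The cKO pair holds the deepest library and the only male, so these values do not rank the groups by replicate noise. Read counts from the Y chromosome marked cKO replicate 3 as male (Ddx3y at 101.6 CPM of the total, Xist at 2.13), while Xist stood between 1770 and 2078 CPM in the other libraries, so the sexes were not balanced between groups.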

Results

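Ventricular RNA was compared between 2 embryos with the Hif1a gene floxed and Cre expressed from the Nkx2-5 locus (cKO) and 2 littermates with the same floxed alleles and no Cre. The comparison asks which transcripts differ in the embryonic ventricle when Hif1a, the oxygen-regulated subunit of the transcription factor HIF-1, is deleted in heart muscle precursors. No group carried the Cre without the floxed Hif1a. Effects of the Cre, or of its place in the Nkx2-5 locus, therefore cannot be separated from those of Hif1a loss for any gene or list. Total expected counts ranged from 8561687 to 19801300 per library, the largest in cKO replicate 3, which was also the only male.

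Hif1a (ENSMUSG00000021109, GRCm38 chromosome 12, 73901375 to 73947530, plus strand) stood at 690 ± 37.9 CPM in cKO and 541 ± 15.8 CPM in control (SD, n = 2 each). Its log2 fold change was 0.35 ± 0.09 (SE), and it did not pass edgeR's quasi-likelihood test (adjusted p = 0.317). DESeq2 called it (adjusted p = 0.0177). A count over the whole gene does not separate the deleted part from the rest, so this value does not check the deletion. Nkx2-5 (ENSMUSG00000015579, chromosome 17, 26838664 to 26845009, minus strand), which encodes a cardiac homeobox factor and carries the Cre, had 43.2 ± 1.56 CPM in cKO and 60.4 ± 6.39 CPM in control. Its log2 fold change of -0.49 ± 0.10 did not pass (adjusted p = 0.153).

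Of the measured genes of glucose breakdown 15 of 22 fell in the cKO ventricles, and of those of the response to low oxygen 7 of 28. Neither list passed camera with an estimated correlation (adjusted p = 0.554 for each, unadjusted p = 0.0303 and 0.0423). That version rests on 2 residual degrees of freedom, and 0.554 was its smallest adjusted p over all 29 lists. Failing it, here or below, therefore says little about whether a list changed. Passing camera at the preset correlation of 0.01 is limited too, since its p values can be too small where genes vary together. The estimated correlation was 0.162 for glycolysis and 0.108 for the hypoxia response. Over the lists that camera called, it ran from -0.029 for amino acid catabolism to 0.751 for erythroid genes. The largest falls among named genes were those of Bnip3, a mitochondrial protein of the BCL2 family induced by hypoxia, and Pdk1, a kinase that restrains pyruvate dehydrogenase. Bnip3 went from 151 ± 10.8 to 33.3 ± 1.8 CPM (log2 fold change -2.18 ± 0.10, adjusted p = 3.15e-05), and Pdk1 from 257 ± 4.80 to 62.2 ± 3.51 CPM (-2.05 ± 0.09, adjusted p = 2.65e-05). Over all 13711 genes, 956 had an unadjusted p under 0.05 in edgeR's test, many of them expected by chance at that threshold. After adjustment 70 passed, 20 higher and 50 lower in cKO. The count was 141 without cKO replicate 2 and 39 without control replicate 3. It was 33 when tested against a 1.5-fold change.

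Of 22 measured glycolysis genes 15 fell, 0 rose and 7 did not pass; 18 fell when adjusted over the list alone. The list's median log2 fold change was -0.86, and it was -0.93 in cKO replicate 2 and -0.77 in cKO replicate 3 against the controls. Pfkl, the liver form of phosphofructokinase, fell 3.09-fold (adjusted p = 6.39e-05), and Ldha, which makes lactate, fell from 1237 ± 15.4 to 414 ± 26.4 CPM (adjusted p = 0.000161). The lactate exporter Slc16a3 fell 3.95-fold (adjusted p = 0.000635), and the glucose transporter Slc2a3 fell by 1.44 on the log2 scale (SE 0.18, adjusted p = 0.0168). The call for Slc2a3 was lost without control replicate 2 (adjusted p = 0.0925) and without control replicate 3 (0.122). Camera placed the list below other genes (adjusted p = 4.15e-25); with an estimated correlation the adjusted p was 0.554.

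Of 28 measured hypoxia-response genes 7 fell, 0 rose and 21 did not pass; 16 fell when adjusted over the list alone. The median log2 fold change was -0.40, with camera's adjusted p = 2.11e-15 and an adjusted p of 0.554 with an estimated correlation. Beside Bnip3, the mitochondrial adenylate kinase Ak4 fell 3.28-fold (adjusted p = 0.000249), the cytokine Mif fell 2.28-fold (adjusted p = 0.00213) and the prolyl hydroxylase Egln1, which marks HIF subunits for destruction, fell by 0.85 on the log2 scale (adjusted p = 0.00391). Vegfa, the endothelial growth factor, chosen after its values were seen, had a log2 fold change of -0.30 ± 0.13 (adjusted p = 0.708). Of 8 measured HIF pathway components none passed edgeR's test, and 1 rose when adjusted over the list alone; Hif1a itself had the smallest p. Igfbp2, a binding protein of insulin-like growth factors outside these lists, fell 3.06-fold (adjusted p = 0.00146).

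**Figure D1:**
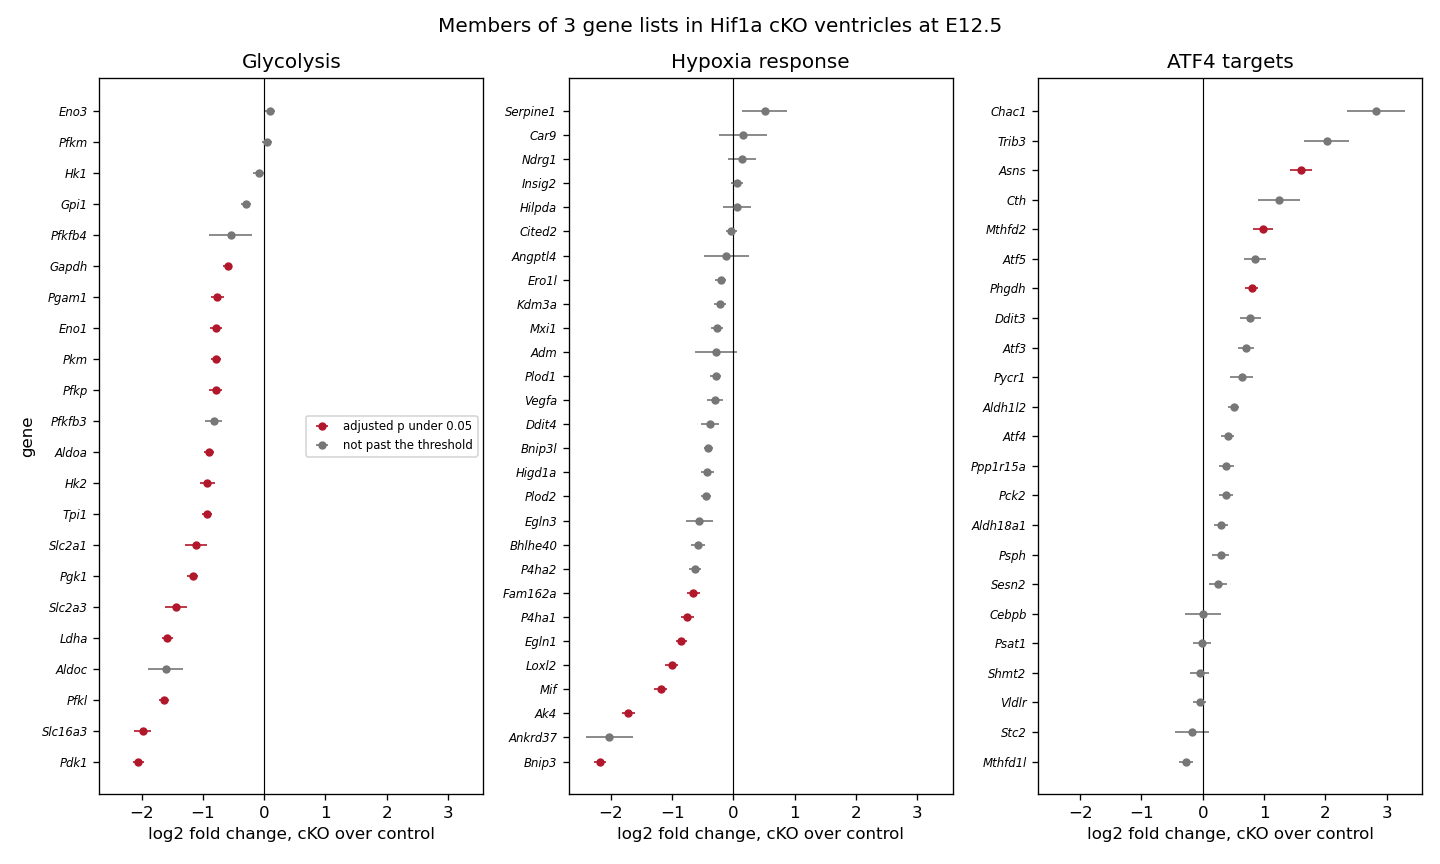
Points give the log2 fold change (cKO over control, 2 libraries each) of every measured member of 3 lists, with bars of 1 SE, and red marks an adjusted p under 0.05. All red points lie below 0 for glycolysis (15) and hypoxia response (7), and above 0 for ATF4 targets (3).

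The ATF4 list is named for the transcription factor that responds to amino acid shortage and other stress. Of 23 measured members 3 rose, 0 fell and 20 did not pass, 5 of them with negative log2 fold changes; 14 rose when adjusted over the list alone. The list's median was 0.41, with camera's adjusted p = 3.64e-10 and an adjusted p of 0.651 with an estimated correlation. Asns, which makes asparagine, rose from 15.8 ± 0.918 to 47.4 ± 11.5 CPM (log2 fold change 1.60 ± 0.17, adjusted p = 0.00594). Phgdh, the first enzyme of serine synthesis, rose 1.74-fold (adjusted p = 0.0172), and Mthfd2, a mitochondrial folate enzyme, rose 1.98-fold (adjusted p = 0.0478). These calls did not hold in each leave-out: Asns lost its call without control replicate 2 (adjusted p = 0.0766) or 3 (0.0706), Phgdh without cKO replicate 3 (0.0652) or control replicate 2 (0.0766). Mthfd2 lost its call without cKO replicate 3 (0.0768), control replicate 2 (0.179) or control replicate 3 (0.229), and under both other filters and limma-voom.

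Slc7a3, a carrier of cationic amino acids on chromosome X, rose from 0.622 ± 0.211 to 8.16 ± 1.67 CPM (log2 fold change 3.70 ± 0.37, adjusted p = 0.00402). It was the 1 of 25 measured amino acid transporters that rose, with 2 when adjusted over the list alone, and that list did not pass (camera adjusted p = 0.241). Camera placed the aminoacyl-tRNA synthetases (median 0.15, adjusted p = 0.00123) and the genes of amino acid catabolism (median 0.088, adjusted p = 0.0015) above other genes. None of their 20 and 29 members passed edgeR's test, though 3 synthetases rose when adjusted over that list alone, and camera's adjusted p was 0.651 and 0.554 with an estimated correlation. Lars and Bcat1 had the smallest p in these lists, with log2 fold changes of 0.41 ± 0.09 and 1.2 ± 0.29; Bcat1 had 0.67 without cKO replicate 3 and 1.54 without cKO replicate 2 (adjusted p = 0.00103). The synthetase call was lost without cKO replicate 3 (median 0.077, adjusted p = 0.134), and the catabolism call without control replicate 2 (median 0.12, adjusted p = 0.166).

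None of the 37 nuclear genes of oxidative phosphorylation passed edgeR's test, yet 36 had a positive log2 fold change. The median was 0.19, and camera's adjusted p was 1.60e-08, against 0.651 with an estimated correlation. The median was 0.29 without control replicate 2 and 0.11 without control replicate 3. The controls themselves differed by a median of 0.15 over the same genes, so the shift was about as large as the difference between replicates of 1 group. The tricarboxylic acid cycle (21 genes, median 0.12, camera adjusted p = 0.00812) and fatty acid oxidation (23 genes, median 0.066, camera adjusted p = 0.0432) had no member past the test, and each had an adjusted p of 0.651 with an estimated correlation. Neither held when any 1 library was left out, with adjusted p values from 0.0514 to 0.0604 and from 0.0594 to 0.244. Sdhb and Echs1, with the smallest p, had log2 fold changes of 0.24 ± 0.08 and 0.27 ± 0.08, and Ndufa5 of the first list had 0.27 ± 0.08.

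Of the lists fixed as markers of cells other than heart muscle, camera placed 4 lower in cKO. Whether their members are specific to those cells in these ventricles was not tested. All 17 endothelial and endocardial genes had negative log2 fold changes (median -0.21, camera adjusted p = 4.25e-05, and an adjusted p of 0.630 with an estimated correlation), none past edgeR's test, Flt1 having the smallest p (-0.29 ± 0.09). Their median was -0.11 without control replicate 3. Of 11 epicardial genes 1 fell, with 3 when adjusted over the list alone (median -0.26, camera adjusted p = 0.000798, and an adjusted p of 0.651 with an estimated correlation). This was the keratin gene Krt19, which went from 43.4 ± 2.87 to 21.7 ± 5.27 CPM (adjusted p = 0.0347) and lost its call without cKO replicate 3 (0.0754), control replicate 2 (0.108) or control replicate 3 (0.260). The smooth muscle and pericyte list (7 genes, median -0.22, camera adjusted p = 0.00772, and an adjusted p of 0.651 with an estimated correlation) had no member past the test, with 2 lower when adjusted over the list alone; Acta2 had -0.63 ± 0.11. The erythroid list (15 genes, median -0.35, camera adjusted p = 0.00309, and an adjusted p of 0.739 with an estimated correlation) rested on cKO replicate 2, where its median stood at -1.02 against the controls, and at 0.016 in cKO replicate 3; without cKO replicate 2 the adjusted p was 0.463. The epicardial call was lost without cKO replicate 3 (median -0.14, adjusted p = 0.157) or control replicate 3 (-0.11, 0.0829), the smooth muscle call without cKO replicate 2 (0.172) or control replicate 3 (0.113), and the erythroid call also without control replicate 2 (0.166).

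None of 23 genes of the sarcomere and calcium handling passed edgeR's test (median -0.038, camera adjusted p = 0.620); Casq2, which stores calcium, had -0.65 ± 0.11 (adjusted p = 0.0651). The lists of cardiac transcription factors (median -0.037), trabecular myocardium (0.13) and compact myocardium (-0.036) did not pass camera. Their members with the smallest p were Nkx2-5, Cpne5 (log2 fold change 0.81 ± 0.14) and Mycn (-0.35 ± 0.12). The 26 cell cycle genes had a median of -0.069 (camera adjusted p = 0.0432, and 0.651 with an estimated correlation), with no member past the test and no call in any of the 4 leave-outs (adjusted p from 0.0627 to 0.343). Mki67, a marker of dividing cells, had a log2 fold change of -0.18 ± 0.09.

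Camera called no other list. Medians were 0.13 for p53 targets (Trp53inp1 at 0.32 ± 0.09), -0.054 for sterol synthesis, -0.016 for NRF2 antioxidant genes (Hmox1 at 1.12 ± 0.37, and at 0.30 without cKO replicate 3) and 0.098 for genes of the mitochondrial genome (mt-Co2 at 0.24 ± 0.13). Among other cells, medians were 0.22 for cushion mesenchyme, -0.080 for atrial and inflow genes, -0.082 for immune cells, -0.053 for neural crest and neural genes (2 measured) and -0.16 for liver (3 measured). The cushion genes split the cKO libraries, with -0.29 in replicate 2 and 0.45 in replicate 3. Col2a1, a cartilage collagen, stood at 20.8 ± 21.6 CPM in cKO and 71.9 ± 9.83 CPM in control. Kcna5 had -1.05 ± 0.36, Slc4a1 -0.66 ± 0.33, Mrc1 -0.75 ± 0.37, Elavl4 -0.24 ± 0.31 and Apoa2 1.89 ± 0.66. Immediate-early genes had a median of 0.066 (Ier3 at -0.53 ± 0.28). For immune cells and liver the sign of the median differed from that of camera's test, for liver also from that of the mean, and for NRF2 genes the median was negative and the mean 0.007.

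**Figure D2:**
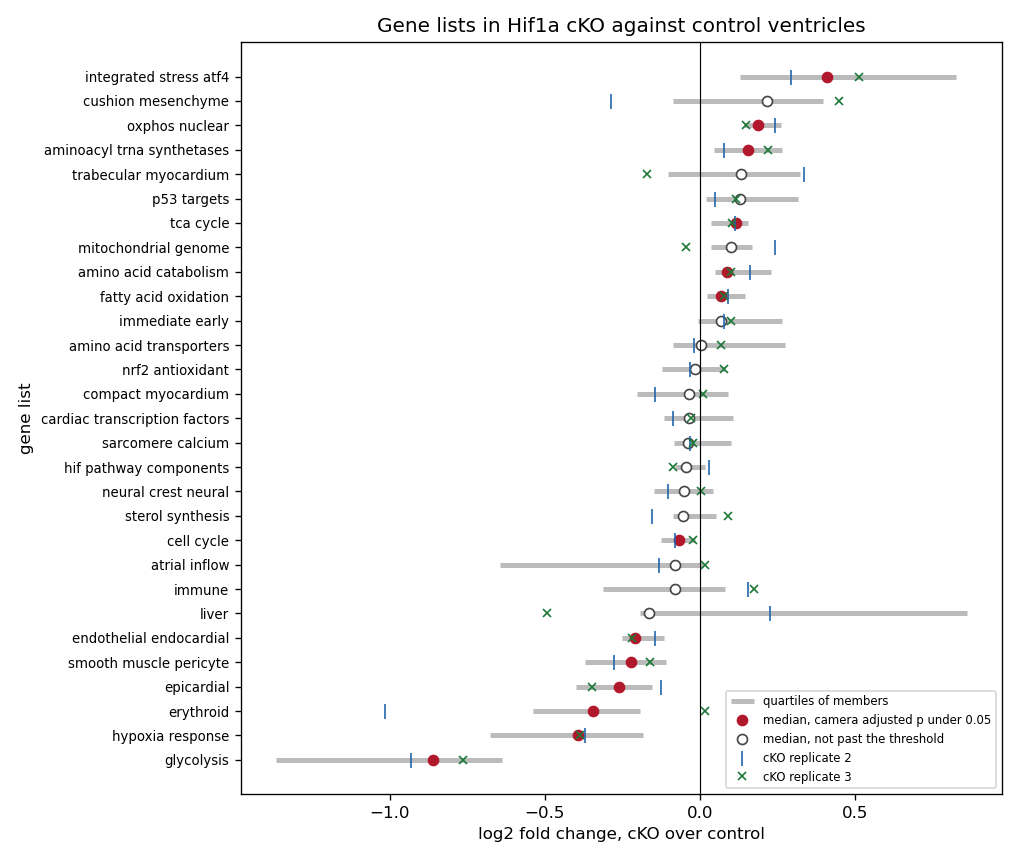
Filled red and open circles give each list's median log2 fold change (cKO over control), grey bars the quartiles of its members, and the ticks and crosses the medians of cKO replicates 2 and 3 against the controls. Glycolysis is lowest at -0.86 and the ATF4 list highest at 0.41, and the erythroid list separates the cKO replicates (-1.02 and 0.016).

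Several of the genes that rose share their sequence with another gene, which makes their values uncertain. Of the 20 genes that rose, 13 have a near-identical copy, against 16 of the 50 that fell. Hmga1b, on chromosome 11, had 30.6 ± 4.84 CPM in cKO and 0 counts in both controls, at least 89.4-fold higher. It matches Hmga1, a chromatin protein gene on chromosome 17, over 1602 bases at 99.8% identity, and Hmga1, chosen after its values were seen like the other copies named here, was lower in cKO (adjusted p = 0.00631). Their sum gave a log2 fold change of -0.42 with no call (adjusted p = 0.331). Nanp, which encodes a sialic acid phosphatase, was at least 20.7-fold higher against 0 counts, and its sum with the chromosome 17 copy Gm6741 gave -0.046 (adjusted p = 0.971). Dynlt1b, a dynein light chain on chromosome 17, was 2.64-fold higher (adjusted p = 0.00146) and lost its call with its copies summed (0.63 on the log2 scale, adjusted p = 0.0902). With every called gene summed with its copies, an alternative chosen after seeing the data, 8 genes or families rose and 40 fell.

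**Figure D3:**
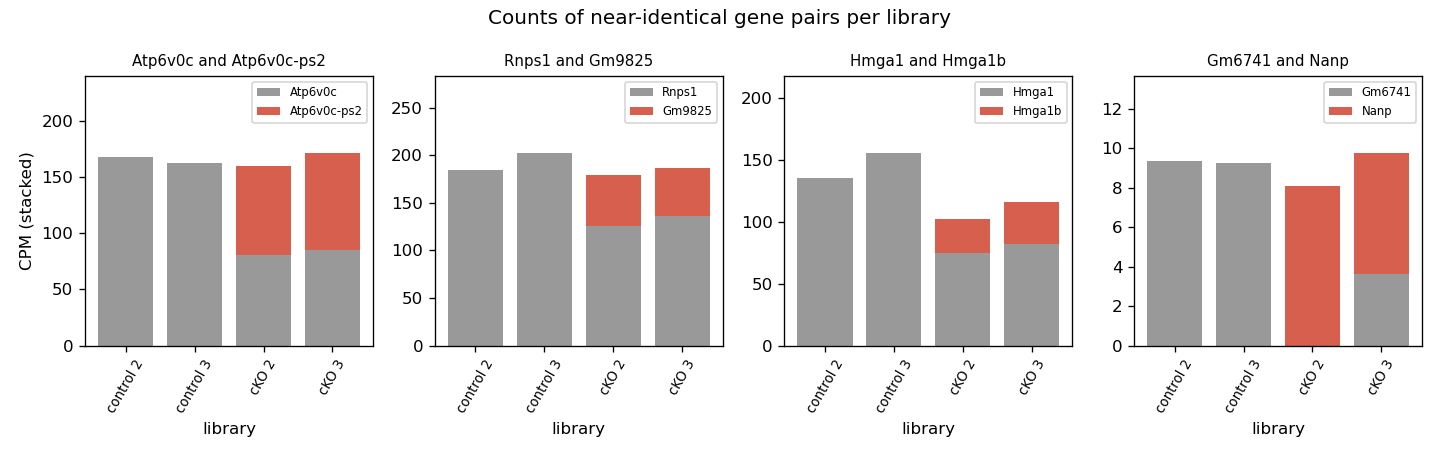
Stacked bars give the CPM of 4 near-identical gene pairs in each library, grey for the gene on chromosome 17 and red for its copy on another chromosome. Copies are at 0 in both controls, and the sums for Atp6v0c are 165 CPM in control and 166 CPM in cKO. Of the 7 such copies with a relative on chromosome 17, the 3 not shown are Rps2-ps10, Gm13443 and Gm14292. For these the sum rose by 63.4%, 364.8% and 99.9% of the copy's CPM. The value for Gm13443 includes a rise of its chromosome 17 relative Glo1 from 117 CPM in control to 161 CPM in cKO.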

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

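Summing copies, thinning cKO replicate 3 and leaving out chromosome 17 or X and Y were chosen after seeing the data. With 2 libraries per group every leave-out assumes that the lone library varies like the other group. The 70 calls included the same 70 genes under DESeq2's size factors and upper-quartile scaling, 67 under DESeq2 and limma-voom, and 69 with the replicate block. The block gave 75 calls; the deviations of same-numbered libraries correlated at 0.106 across genes, and the labels tie the numbers to no shared source. Genes that rose numbered 20, against 10 with the stricter filter, 31 with DESeq2 and 8 with copies summed. Against a 1.5-fold change 33 were called, 18 of them lower. Leaving out 1 library gave 39 to 141 calls, 15 to 72 risen and 24 to 69 fallen. Hif1a (0.35) passed under DESeq2 only, where its log2 fold change was also 0.35 (adjusted p = 0.0177; range over all settings 0.0177 to 1). Of the 13 called lists, 0 passed with an estimated correlation or fry, and 8 passed in each leave-out, but only 5 in all 4 (glycolysis, hypoxia response, oxidative phosphorylation, ATF4 and endothelial), and 2 to 4 others were newly called. These were amino acid transporters, p53 targets and cushion without cKO replicate 2, mitochondrial genome, sterol synthesis, trabecular and cushion without cKO replicate 3, mitochondrial genome and immune without control replicate 2, and immune and immediate-early without control replicate 3. Fry's mixed test, which ignores direction, passed only glycolysis (adjusted p = 0.00866), hypoxia response (0.0149) and amino acid catabolism (0.0208) among the called lists. The replicate block and no filter each kept 11 of the 13, losing fatty acid oxidation and cell cycle. Thinning lost cell cycle, and leaving out chromosome 17 lost fatty acid oxidation. The cause of these differences was not tested, except that fewer genes enter the stricter filter. With copies summed, Hmga1b turned to -0.42 and Nanp to -0.046. Without the filter the medians of atrial (0.015), neural (0.14) and liver (1.62, adjusted p = 0.0314) genes turned positive, and with the block that of amino acid transporters turned to -0.013. With 1 library left out, the medians of 16 lists changed sign within their range, of which the erythroid list alone was called in the full data: HIF components -0.091 to 0.028, mitochondrial genome -0.046 to 0.25, amino acid transporters -0.022 to 0.074, sterol synthesis -0.16 to 0.089, NRF2 -0.064 to 0.0735, sarcomere -0.032 to 0.037, cardiac factors -0.087 to 0.0005, trabecular -0.17 to 0.33, compact -0.15 to 0.010, cushion -0.30 to 0.59, atrial -0.35 to 0.022, erythroid -1.08 to 0.0089, immune -0.63 to 0.64, neural -0.12 to 0.27, liver -0.55 to 0.20 and immediate-early -0.12 to 0.29. Mrc1 ranged from -1.28 to 0.14. Of genes named without a call, Bcat1, Hmox1, Casq2 and Col2a1 were called without cKO replicate 2, Acta2, Slc4a1 and Col2a1 without cKO replicate 3, and Mrc1 without control replicate 2. The cushion list passed camera in opposite directions without cKO replicate 2 (adjusted p = 0.000143) and 3 (0.000657), and so did the immune list without control replicate 2 (0.000114) and 3 (9.31e-06). In the simulation, with 2 libraries per group at these depths, 49.0% of 1.5-fold changes were called. The simulation had 183 calls against 70 here, so the share in the real data may be lower.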

Other observations

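Except for the comparison with matched random lists and the leave-out, the tests in this part were chosen after the result was seen, and so were the genes named in the next paragraph. For the other genes of chromosome 17, the spread within which a value settles nothing was also required only after the value was seen; without it the test would have counted against the explanation. The thinned library was likewise labelled undecided only after it was seen to move the other lists little.

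Several called genes outside the fixed lists also act on sugar phosphates and glycogen. Pygl, a glycogen phosphorylase, fell from 45.6 ± 2.00 to 20.1 ± 0.240 CPM (SD, n = 2 each, edgeR adjusted p = 0.00129). Pgm1, which interconverts glucose phosphates, had a log2 fold change of -0.58 ± 0.08 (SE, edgeR adjusted p = 0.0239), and Galk1, which phosphorylates galactose, -0.72 ± 0.10 (edgeR adjusted p = 0.0200). Ppp1r3g, which targets a phosphatase to glycogen, went from 4.05 ± 0.119 to 0.454 ± 0.216 CPM (edgeR adjusted p = 0.0200). No list of such genes was fixed beforehand, so their number was not tested against chance. Ddc, the decarboxylase that makes dopamine and serotonin, fell 1.83-fold (edgeR adjusted p = 0.0126), and Mgarp, a mitochondrial protein, went from 3.07 ± 0.333 to 0.328 ± 0.109 CPM (edgeR adjusted p = 0.0238).

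Of the 20 genes that rose, 10 had 0 counts in both controls, and 9 of these have a near-identical copy; for 7 of the 9 the most abundant copy lies on chromosome 17, which carries Nkx2-5 and therefore the Cre, while 4.69% of tested genes lie there (Fisher's exact test, one-sided, p = 1.61e-08), and a candidate explanation is variant DNA inherited with the Cre allele, whose reads RSEM would assign to a relative elsewhere. Other genes of chromosome 17 did not settle it, since 15 of 622 had p under 0.01 against 218 of 12876 elsewhere (Fisher's exact test, one-sided, p = 0.12, odds ratio 1.43, 95% interval 0.784 to 2.44), with 2.17% below 50 Mb, where Nkx2-5 lies, and 3.11% beyond, while 5 of the 7 copies lie within 4 Mb of Nkx2-5, Wtap at 12966796 and Gm6741 far from it at 91236811. Called genes at or near 0 in 1 group also have copies off chromosome 17: Gm3608 (1.79 to 72.2 CPM, copy Capza1 on chromosome 3, log2 ratio of the sums -0.053), and 3 genes at 0 in both cKO libraries (Gm10146, Gm2223 and Gm21970, copies Lsm7 on chromosome 10, Eif2s3x on X and Il10rb on chromosome 16). If reads only moved, each gene's sum with its copies should stay level: the median rise was 0.7% of the copy's own CPM, but the quartiles ran from -19.5% to 63.4%, so moved reads and transcription of the copies after loss of Hif1a cannot be told apart over all 9. The sum rose by at least 50% of the copy's CPM for 3 of them, Rps2-ps10, Gm13443 and Gm14292. For Gm14292 the rise was 5.46 CPM, less than the SD of 7.68 of its control sum. For Gm13443 the rise of 61.25 CPM was larger than the copy's own 16.8 CPM. Its relative Glo1 itself went from 117 to 161 CPM, so that rise does not measure the copy alone. The sum did not rise that far for the other 6: Pagr1b 22.0%, Atp6v0c-ps2 0.7%, Nanp -5.3%, Gm9825 -19.5%, Hmga1b -119%, and Gm5537, whose copy Pgk1 was itself lower.

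The ATF4 list stood above a trend with expression, transcript length or GC content: its median was at percentile 100 of 10000 random lists matched on these, a test written before its result was seen. Of the 13 called lists, fatty acid oxidation alone lay within the central 95% of its matched lists (percentile 93.4). Only lists already called on the same values were compared, and the random genes were drawn independently. The comparison therefore adds no support for a list beyond a median outside that of genes matched on these traits. For oxidative phosphorylation the central 95% of the matched medians lay above 0, from 0.005 to 0.116, against 0.185 for the list. Part of that shift was thus shared by matched genes. The erythroid list, which rested on cKO replicate 2, also lay outside its matched lists. Thinning the deeper cKO replicate 3 to the mean depth of the others left the ATF4 median at 0.411, but moved the 28 other lists by a median of only 0.012, so it decides nothing. Without that library, which is also the only male, the list kept its call (median 0.29, camera adjusted p = 7.21e-05 at the preset correlation), so the call does not need it, though this rests on 1 cKO library and part of the larger median in cKO replicate 3 (0.51) stays open. Other differences between these embryos cannot be separated from genotype with 2 libraries per group, and a response to the loss of Hif1a was not tested.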
